A study of Mus musculus with 8 samples.

How the data were processed

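H3K27me3 ChIP and input libraries of mouse chondrocytes from cartilage were sequenced for 4 genotypes, 1 ChIP and 1 input library each. Per the submitters' processing notes, FastQC 0.11.5, Bowtie2, MACS2, HOMER 4.10, deepTools 2.4.1 and ChIPseeker were used. The Bowtie2 version and the genome build are not given in the sources used here. Per the file headers, the authors called broad peaks with MACS 2.1.2 from paired-end fragments of each ChIP library against the input of the same genotype, not on pooled samples, at a q of 0.05 and a broad threshold of 0.05, keeping at most 1 duplicate fragment per position and scaling the larger library down to the smaller. The 4 deposited peak lists were analysed. In them the authors give each peak's pileup as a coverage signal, its −log10 p and −log10 q against the input, its fold enrichment as a ratio over the local input, and its length in bp. Pileup was not compared between libraries. Because each list is scaled to its own library pair and its threshold depends on depth, a gene can enter or leave a list without any change in the mark.

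Genes came from the RefSeq table of GRCm38.p6, with 21883 protein-coding genes on chromosomes 1 to 19, X and Y. The build of the files was settled from the names of their unplaced scaffolds and from a shift test. Aligned to the table, the wild-type peaks marked 13635 genes, against 4836 and 4789 when gene positions were moved by 20 kb in either direction. Over 60 segments of the chromosomes, the smallest ratio of aligned to moved counts was 1.51. The table gives gene starts and ends without strand or exons, and no genome sequence was used here. The planned promoter windows around transcription start sites were therefore replaced by windows of 2 kb around either gene end, with 5 kb for the absence of a peak, and a peak at a gene's 3' end counts too. Planned matching of random gene lists on CpG density was not done, and unmatched random lists were used, with lists matched on gene length added after the data were seen. Exons and introns were not told apart.

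Peaks counted as overlapping from 1 bp. Chance overlap is the mean of 100 shuffles within chromosomes with a fixed seed. The 16 gene lists, with 394 entries that all matched the table, 1 of them through a synonym, were fixed in advance, as were the comparisons and the rule for named genes. That rule took, per knockout, the 10 genes with the highest fold enrichment among those marked in the knockout and without a wild-type peak within 5 kb, and the 10 in the converse set, 1 gene per peak. It also took up to 4 members per list, those marked in 1 list alone first, and Ezh2, Kdm6a, Kdm6b, Wnt10a, Ihh, Runx2, Sox9, Col2a1, Col10a1, Mmp13 and Cdkn2a. Other list members named in the report were chosen after their values were seen, where a list gained or lost them. Some genes that the rule names are not reported here. With 1 library per genotype no test between genotypes was made and no p-value is given. Percentiles of a list among 10000 random lists describe these libraries.

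The alternatives fixed before the data were examined were peaks with q of 0.001 or less, peaks with fold enrichment of 4 or more, the same number of strongest peaks per list, merging of peaks within 3 kb, autosomes only, an overlap of 50% of the shorter peak, and windows of 1 and 5 kb. A peak anywhere over the gene was added after the data were seen. The gene marking and overlap steps were tested on simulated peaks: all 111 genes given a peak were found (100%) among 21883 searched. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Peaks on unplaced scaffolds were left out of gene-based results.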

Results

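Histone H3 trimethylated at lysine 27 (H3K27me3), a mark deposited by the Polycomb enzyme Ezh2 and removed by the demethylases Utx (Kdm6a) and Jmjd3 (Kdm6b), was profiled by chromatin immunoprecipitation and sequencing in mouse chondrocytes, the cells of cartilage. The question was how the mark differs when Ezh2, Utx or Jmjd3 is conditionally deleted (cKO). There were 8 libraries: 1 immunoprecipitated (ChIP) library and 1 input library for each of 4 genotypes, namely wild type, Ezh2-cKO, Utx-cKO and Jmjd3-cKO. After removal of duplicates the ChIP libraries held 29222251 fragments in wild type, 34786292 in Ezh2-cKO, 34359111 in Utx-cKO and 25655346 in Jmjd3-cKO. The inputs held 16599532, 24041619, 23983492 and 16645811 fragments in the same order. With n = 1 per genotype no difference has a replicate check, and intervals are 95% Wilson intervals that cover counting error only. The library titles carry a prefix that differs between wild type, Ezh2-cKO and the pair of demethylase knockouts, so library batch and genotype cannot be told apart, except between Utx-cKO and Jmjd3-cKO, which share a prefix. A gene is called marked when a peak lay within 2 kb of either of its ends. H3K27me3 is the mark that the labels give. Values under Other observations argue against a profile that follows Polycomb target genes as a whole, and a mark of active promoters remains a candidate there. A marked gene is therefore not read here as a repressed one. Fold enrichment is the authors' value for a peak over its own input, and it ranks peaks within a list only. Its median at marked genes was 6.41 in wild type, 7.21 in Ezh2-cKO, 8.65 in Utx-cKO and 7.96 in Jmjd3-cKO. The alternative cut at fold enrichment of 4 is therefore not equal between lists, and differences at that cut can follow this scale.

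The targeted genes were marked in all 4 genotypes. The strongest peak at Ezh2 lay on chromosome 6 at 47593600 to 47596011 in wild type, with fold enrichment 9.02, and the Ezh2-cKO list held a peak at 47593221 to 47596017. Kdm6a on chromosome X had a wild-type peak at 18161480 to 18165206 and a Utx-cKO peak at 18161370 to 18165337. Kdm6b on chromosome 11 had a wild-type peak at 69408220 to 69420569, and a Jmjd3-cKO peak spanned 69407247 to 69421791. A peak list does not show whether a part of a gene was deleted, so these peaks do not check the genotype labels. Coordinates are those of the authors' peaks and match the GRCm38 gene positions, as tested on the peaks themselves.

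In wild-type chondrocytes the cartilage genes were among the marked genes. Marked means a called peak in a library labelled H3K27me3, and which mark the peaks show stays open (Other observations). Of 28 genes of the chondrocyte matrix and its regulators, 24 were marked (85.7%, 68.5 to 94.3%), among them Sox9, the master regulator of chondrocyte fate, with fold enrichment 7.77, Trps1 with 9.22 and Col11a1 with 8.61. Col2a1, the main collagen of cartilage, carried a peak of 16587 bp on chromosome 15 from 97989326 to 98005912, the 7th longest of the list. The longest wild-type peak, 34271 bp on chromosome 15 from 102959322 to 102993592, covered the ends of Hoxc8, Hoxc9 and Hoxc10. Hypertrophy genes were divided: Ihh and Runx2 were marked, with fold enrichment 3.39 and 4.09, whereas Col10a1, the collagen of hypertrophic cartilage, and the collagenase gene Mmp13 had no peak within 5 kb in any of the 4 lists.

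**Figure D1:**
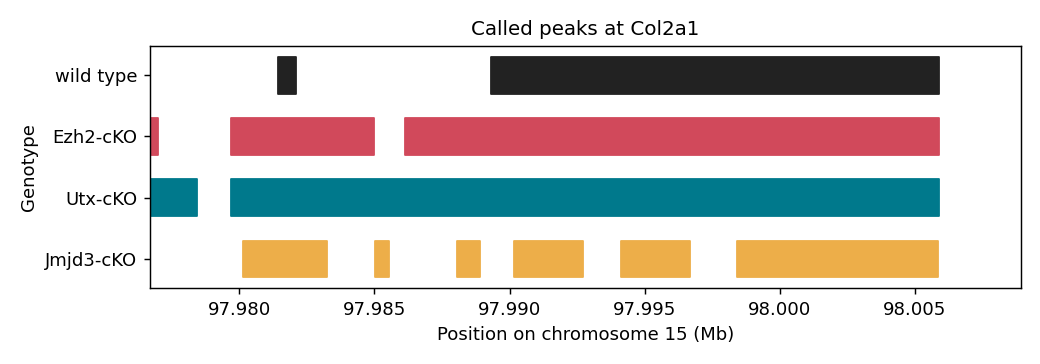
Called peaks around Col2a1, with position on chromosome 15 in Mb on the horizontal axis, 1 row per genotype and 1 bar per peak. The peak with the highest fold enrichment measured 16587 bp in wild type, 19793 bp in Ezh2-cKO, 26223 bp in Utx-cKO and 7451 bp in Jmjd3-cKO. Weaker peaks lay beside it in each genotype, with the most in Jmjd3-cKO. Together the peaks within 5 kb of the gene covered 17251 bp in wild type, 27675 bp in Ezh2-cKO, 30203 bp in Utx-cKO and 17071 bp in Jmjd3-cKO.

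Across the other groups, all 9 cell cycle inhibitor genes, including Cdkn2a and Rb1, were marked in wild type, as were 28 of 30 housekeeping genes (93.3%, 78.7 to 98.2%), such as Hnrnpk and Vcp, and 14 of 14 genes of PRC2 and the H3K27 demethylases. Ligands and antagonists of the TGF-beta and BMP pathways were marked in 31 of 36 cases, Hedgehog pathway genes in 14 of 16, Wnt ligands and antagonists, Wnt10a among them, in 26 of 34, and tendon and synovium genes in 18 of 20. Marked genes were fewer among transcription factors of other lineages, with 17 of 45 (37.8%, 25.1 to 52.4%), a share at percentile 0.045 of 10000 random gene lists of the same size and 0.555 of lists also matched on gene length. Myogenic genes (5 of 15), endothelial markers (5 of 16) and haematopoietic markers (7 of 20) also lay low, at percentiles 1.49, 0.775 and 0.77, or 2.775, 0.145 and 1.175 with matched lists. Hox genes, with 29 of 39, lay high instead, at percentile 94.1, or 99.98 with matched lists. Neighbouring Hox genes can share a peak, as Hoxa7, Hoxa9, Hoxa10 and Hoxa11 did in wild type. Percentiles and intervals of the Hox list therefore treat its genes as more independent than they are. These percentiles describe the libraries and are not tests.

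The wild-type list held 28057 peaks covering 40.5 Mb, and 13635 of 21883 protein-coding genes were marked (62.3%, 61.7 to 62.9%). Of these peaks 43.4% (42.8 to 44.0%) were centred within 2 kb of a gene end, 37.3% elsewhere inside a gene and 19.3% outside protein-coding genes. Among the 11716 peaks with a fold enrichment of 4 or more, 78.4% were centred at a gene end. In the knockouts the share at gene ends over all peaks was 38.9% in Ezh2-cKO, 29.4% in Utx-cKO and 45.2% in Jmjd3-cKO, and 77.3%, 71.1% and 76.4% among those with fold enrichment of 4 or more. A set of 13206 genes was marked in all 4 lists and 6802 genes in none.

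In chondrocytes labelled Ezh2-cKO, marked genes were not fewer than in wild type. Cartilage genes were marked in 25 of 28 cases, Chad being the gene added, with Sox9 and Trps1 marked in both lists. The Hox list went from 29 to 31 of 39, with Hoxb6, Hoxb7, Hoxb8 and Hoxd11 marked in the knockout and not in wild type, and Hoxb2 and Hoxd13 the converse. With a window of 1 kb this difference turned to -2.56 percentage points. Among transcription factors of other lineages 21 of 45 were marked, those added being Pax2, Hand1, Nkx2-1 and Sox17, with fold enrichments of 3.49, 3.36, 2.72 and 2.59. This gain of 4 fell to 1 at q of 0.001 or less, and to 2 both at fold enrichment of 4 or more and with equally long lists.

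The Ezh2-cKO list had 33739 peaks over 48.1 Mb, 1.20 times the wild-type number, and 14114 marked genes. Of the wild-type peaks 80.7% (80.3 to 81.2%) were overlapped by an Ezh2-cKO peak, against 4.01% when peaks were shuffled within chromosomes. Conversely 33.5% (33.0 to 34.0%) of the Ezh2-cKO peaks lay outside wild-type peaks, with a median fold enrichment of 2.58. Genes marked in Ezh2-cKO with no wild-type peak within 5 kb numbered 479, and 153 were marked in wild type with no Ezh2-cKO peak within 5 kb. Genes marked in Ezh2-cKO and in no other list numbered 99. The strongest of the 479 were Akain1, the retinal homeobox gene Vsx1, Slc25a48, the defensin gene Defb14, Tmem26, Grid2ip, Cyp4f37, the oestrogen receptor gene Esr2, A530016L24Rik and Hoxb8, with fold enrichments from 4.70 at Akain1 to 3.72 at Hoxb8. All of these were marked in Utx-cKO too, and all but Vsx1 in Jmjd3-cKO. The strongest of the 153 were Dynlt1b, Ermard, Zfp994, Ear10, Kdm5d, Rnaset2b, 1700016K19Rik, Magee2, Btn2a2 and Ddx3y, from 6.12 at Dynlt1b to 3.66 at Ddx3y. Kdm5d and Ddx3y lie on chromosome Y, and the others named were each marked in another knockout. Wnt ligands and antagonists stayed at 26 of 34, with Sfrp5 added and Dkk1 missing, and TGF-beta and BMP genes went from 31 to 30, with Mstn added and Bmp8a and Lefty2 missing, a direction that turned to 13.9 points above wild type at fold enrichment of 4 or more. Haematopoietic markers went from 7 to 9 of 20, through Tal1 and Cd3e, endothelial markers from 5 to 6, through Sox17, and matrix degradation and inflammation genes from 18 to 17 of 30, without Lif. The last difference turned to 10.0 points above wild type at fold enrichment of 4 or more, and to 3.33 above at q of 0.001 or less and with a window of 1 kb. Hypertrophy, Hedgehog, myogenic, adipogenic, tendon, cell cycle and housekeeping lists had equal counts in both lists.

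In Utx-cKO chondrocytes more developmental regulators were marked than in wild type. Transcription factors of other lineages went from 17 to 34 of 45 (75.6%, 61.3 to 85.8%), and none was marked in wild type and not in Utx-cKO. Those added included Hand1 (fold enrichment 4.97), a regulator of heart development, Eomes (3.35) and T (3.29). Pax2 (3.11), Pax6 (2.57), Sox2 (2.68), Nkx2-1 (2.87) and Nkx2-5 (3.15) were also added. The 17 added genes lay low in the list, with a median fold enrichment of 3.10 and a median rank percentile of 6.70 among marked genes. The difference of 37.8 percentage points lay at percentile 100 of random lists, as did that of 17.8 in Jmjd3-cKO, while that of 8.89 in Ezh2-cKO lay at 97.6. Random lists were not matched on genes unmarked in wild type, 28 of 45 here against 8248 of 21883, so this list could gain more. Of the 28, 60.7% (42.4 to 76.4%) gained a peak in Utx-cKO, against 15.5% of the 8248. The shares were 28.6% (15.3 to 47.1%) against 5.77% in Jmjd3-cKO. In Ezh2-cKO they were 14.3% (5.70 to 31.5%) against 8.40%, which lies inside the interval. The Utx-cKO share itself stood at percentile 86.85, or 98.11 with matched lists. Myogenic genes went from 5 to 10 of 15, through Des, Mymk, Pax7, Pax3 and Myf5, and endothelial markers from 5 to 9 of 16, through Egfl7, Sox18, Esam and Sox17. The myogenic gain was absent with equally long lists, at 5 of 15 in both. It was 5 against 4 in wild type at q of 0.001 or less and 3 against 2 at fold enrichment of 4 or more. With windows of 1 and 5 kb it was 9 against 4 and 12 against 5.

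Signalling and cartilage lists moved by fewer percentage points, though not always by fewer genes. Neighbouring genes can share a peak, as Wnt3 and Wnt9b do in Utx-cKO and Hoxb7 and Hoxb8 do in each knockout. The Hox genes added thus rest on 3 distinct peaks for 4 genes in Ezh2-cKO, 5 for 6 in Utx-cKO and 6 for 7 in Jmjd3-cKO, and the 5 Wnt genes below on 4. Wnt ligands and antagonists went from 26 to 31 of 34, with Sfrp5, Wnt3a, Wnt3, Wnt9b and Rspo4 added, and Hox genes from 29 to 33 of 39, with Hoxd11, Hoxb7, Hoxb8 and Hoxb4 strongest among those added and Hoxb2 and Hoxd4 missing. Hypertrophy and osteogenesis genes went from 18 to 21 of 28, Pth1r and Mepe being among those added, and matrix degradation and inflammation genes from 18 to 21 of 30, through Tnf, Nos2 and Il6. Adipoq and Fabp4 took the adipogenic list from 9 to 11 of 14, and Tal1, Cd3e and Csf1r the haematopoietic list from 7 to 10 of 20. Chad, Mstn and Disp2 were the single additions to the chondrocyte, TGF-beta and BMP, and Hedgehog lists. With equally long lists the chondrocyte difference turned to -3.57 points and that of TGF-beta and BMP genes to -2.78. Housekeeping, tendon and cell cycle lists had equal counts in both lists.

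The Utx-cKO list was the longest, with 49405 peaks over 74.3 Mb, 1.76 times the wild-type number, and 14816 marked genes. It overlapped 87.3% (86.9 to 87.7%) of the wild-type peaks, against 6.0% by chance, and 52.2% (51.8 to 52.6%) of its own peaks lay outside wild-type peaks, with a median fold enrichment of 2.75. The share outside fell to 25.8% with equally long lists and to 21.3% at fold enrichment of 4 or more. Genes marked in Utx-cKO with no wild-type peak within 5 kb numbered 914, against 63 in the converse set, and 562 genes were marked in Utx-cKO and in no other list. Fold enrichment was 4 or more at 38 of the 914 (4.16%) and at 6 of the 63 (9.52%). The strongest of the 914 were Bri3, with a peak of 9425 bp and fold enrichment 9.81, Srp54b (6.72), Asphd1, Dnah7c, Pik3c3, Zfp575, Hand1, the calcitonin gene Calca, Tmem26 and Insc. All of these but Srp54b were marked in another knockout too. In the converse set the strongest were Dynlt1b, Ermard, 5730507C01Rik, Kdm5d, Rnaset2b, Serpinb1b, Olfr1033, Ddx3y, Xirp2 and H2-Q2. All of these but Kdm5d and Ddx3y were marked in another knockout. When each list was limited to its 27013 strongest peaks, the counts were 482 and 182, and 26 developmental regulators were marked in Utx-cKO against 17 in wild type. With fold enrichment of 4 or more, the difference in developmental regulators was 5 genes.

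In Jmjd3-cKO chondrocytes, Hox genes and developmental regulators were again more often marked than in wild type. Hox genes went from 29 to 34 of 39 (87.2%, 73.3 to 94.4%), Hoxb4 to Hoxb8, Hoxb13 and Hoxd11 being added and Hoxb2 and Hoxc12 missing, a difference at percentile 99.93 of random lists. Transcription factors of other lineages went from 17 to 25 of 45 (55.6%, 41.2 to 69.1%), the strongest of those added being Eomes (3.67), Pax8 (3.64), Sox2 (3.38) and Nkx2-1 (3.21). Hypertrophy genes went from 18 to 16 of 28, Panx3 and Runx3 being marked in wild type and not in Jmjd3-cKO. TGF-beta and BMP genes went from 31 to 29 of 36, with Mstn added and Nodal and Lefty2 among those missing. At fold enrichment of 4 or more, a cut that is not equal between lists, their share was 13.9 points above wild type.

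Wnt genes went from 26 to 28 of 34, with Sfrp5, Rspo4 and Wnt8b added and Dkk1 missing, while Chad, Pax3 and Adipoq were the single additions to the chondrocyte, myogenic and adipogenic lists. At q of 0.001 or less the chondrocyte difference turned to -3.57 points. Tal1 was added and Fcer1g was missing among haematopoietic markers, which stayed at 7 of 20. The other lists had equal counts, except that Uty, the Y-linked relative of Utx, was marked in wild type and in none of the 3 knockouts.

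The Jmjd3-cKO list had 27013 peaks over 41.4 Mb, 0.963 times the wild-type number, and 13781 marked genes. It overlapped 75.8% (75.2 to 76.3%) of the wild-type peaks, against 3.33% by chance, and 22.0% (21.5 to 22.5%) of its peaks lay outside wild-type peaks, with a median fold enrichment of 2.77. Genes marked in Jmjd3-cKO with no wild-type peak within 5 kb numbered 348, of which some were marked in other knockouts too, and 56 genes were marked in Jmjd3-cKO and in no other list. The 348 were led by Pik3c3 (5.95), Gm38699, Asphd1, the class II gene H2-Ab1, Dnah7c, Thegl, Lipo2, Akain1, Kcnn4 and Aldh1a2, a gene of retinoic acid synthesis. The converse set, marked in wild type with no Jmjd3-cKO peak within 5 kb, held 240, led by Gm13286 (8.65), Gm40469 (8.56), Zfp33b (7.19), Gm3636, Rsl1, Zfp729b, Gm8108, Gm2237, Gm28455 and Ear10. All of these were marked in Utx-cKO as well, and all but Ear10 in Ezh2-cKO, so among the 4 libraries their absence was not shared by the other knockouts, Ear10 apart. The order of peak numbers turned at stricter thresholds. Jmjd3-cKO had 1.05 times the wild-type number at q of 0.001 or less. It had 1.11 times at fold enrichment of 4 or more, a cut that is not equal between lists. At that cut 880 genes were marked in Jmjd3-cKO with no wild-type peak of the same strength within 5 kb, and 158 were in the converse set. Weaker peaks, which many of these genes have in the other list, are not counted there.

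**Figure D2:**
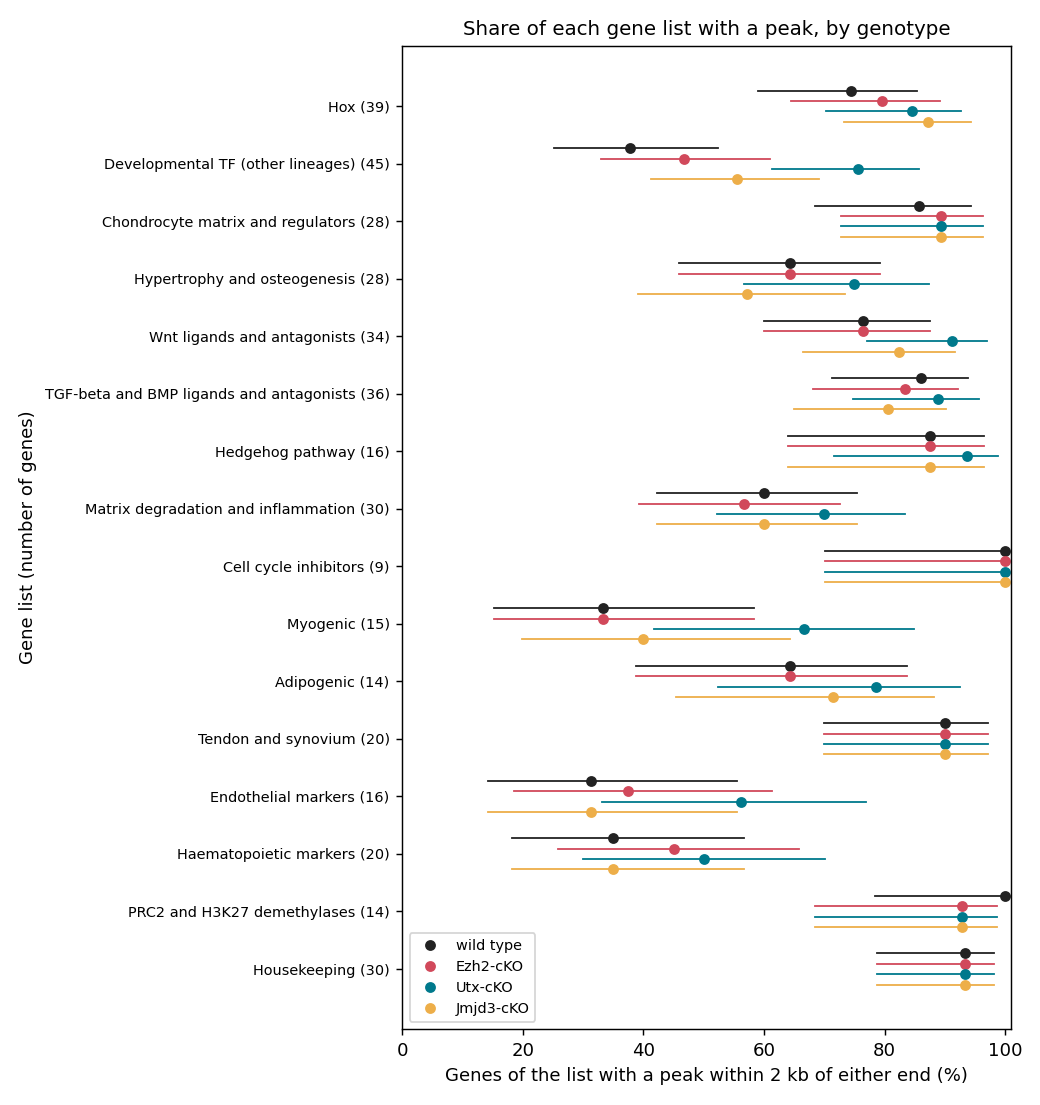
Share of each gene list with a peak within 2 kb of either gene end (horizontal axis, percent), for the 16 lists on the vertical axis with their number of genes. Points are the 4 genotypes, 1 library each, and lines are 95% Wilson intervals; transcription factors of other lineages run from 37.8% in wild type to 75.6% in Utx-cKO, while housekeeping genes stand at 93.3% in all 4.

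Between the demethylase knockouts, Nkx2-1, Sox2, Hand1, Eomes and Cdx2 were among the genes added to the marked genes in both, whereas Pax8 and Olig1 were added in Jmjd3-cKO and not in Utx-cKO. Of the Jmjd3-cKO peaks 89.9% (89.5 to 90.2%) were overlapped by a Utx-cKO peak, against 6.18% by chance, and of the Utx-cKO peaks 47.7% (47.3 to 48.2%) were overlapped by a Jmjd3-cKO peak, against 3.44%. With the 27013 strongest peaks of each, the shares were 78.2% and 75.4%.

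Peaks with high fold enrichment were common to the genotypes. In the quartile of wild-type peaks with the highest fold enrichment, 99.9% were overlapped in Ezh2-cKO, 99.96% in Utx-cKO and 99.8% in Jmjd3-cKO. In the quartile with the lowest, the shares were 60.5%, 77.2% and 48.3%.

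**Figure D3:**
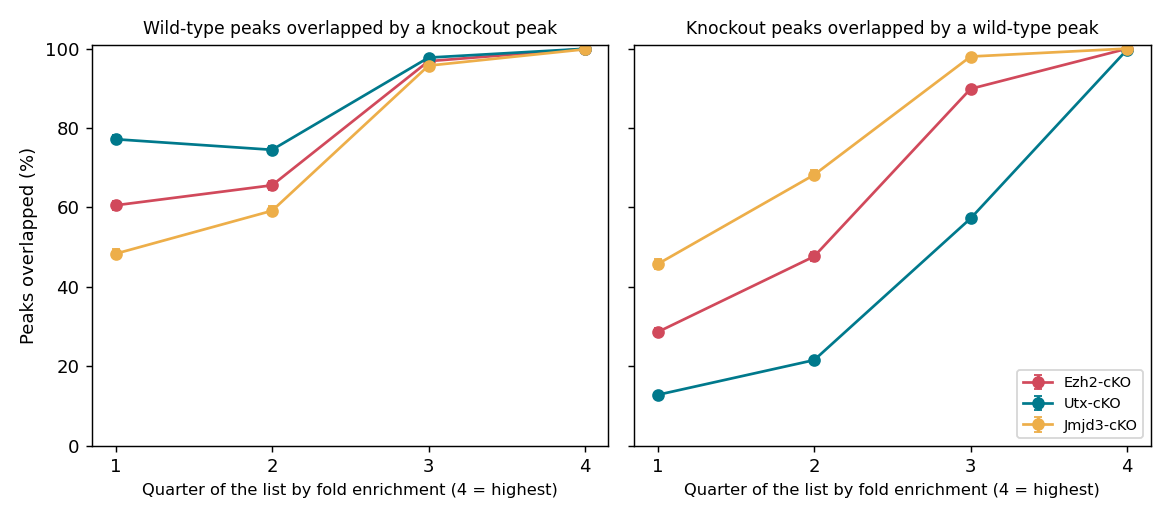
Share of peaks overlapped (vertical axis, percent) by quartile of fold enrichment within the list (horizontal axis, 4 the highest), for wild-type peaks on the left and knockout peaks on the right. Bars are 95% Wilson intervals; in the lowest quartile 12.8% of the Utx-cKO peaks were overlapped by a wild-type peak, and in the highest 99.7%.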

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

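The tests of depth and of Utx loss were chosen after the results they measure were seen, and the ribosomal and homeobox gene lists after the shares of the 16 fixed lists were seen but before their own. None of the differences in direction between knockouts was tested, since each genotype has 1 library.

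Knockouts lay on opposite sides of wild type in the number of peaks: 33739 in Ezh2-cKO and 49405 in Utx-cKO were above the 28057 of wild type, and 27013 in Jmjd3-cKO was below, but Jmjd3-cKO turned to 1.05 times wild type at q of 0.001 or less and 1.11 times at fold enrichment of 4 or more. Marked genes of hypertrophy and osteogenesis numbered 18 in wild type, 21 in Utx-cKO and 16 in Jmjd3-cKO. Marked genes of the TGF-beta and BMP list numbered 31 in wild type, 32 in Utx-cKO, 30 in Ezh2-cKO and 29 in Jmjd3-cKO, but Ezh2-cKO and Jmjd3-cKO turned to 13.9 points above wild type at fold enrichment of 4 or more, and Utx-cKO to -2.78 with equally long lists. Those of matrix degradation and inflammation numbered 18 in wild type, 21 in Utx-cKO and 17 in Ezh2-cKO, which turned to 10.0 points above wild type at fold enrichment of 4 or more and to 3.33 above at q of 0.001 or less and with a window of 1 kb. The values at fold enrichment of 4 or more can follow the scale of each list, which was lower in wild type. Outside the comparisons, unplaced scaffolds held 7 peaks in wild type, 7 in Ezh2-cKO, 7 in Utx-cKO and 6 in Jmjd3-cKO, above the 3 counts that a count of 0 allows.

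The longer Utx-cKO list with more marked developmental regulators has 3 explanations that remain open, of which depth and list length do so only because, after the values were seen, a bound had to be passed by its spread and 1 library of another genotype could exclude nothing. Depth is one: Ezh2-cKO, sequenced to the same depth, had 0.683 times as many peaks, but it is a single library of another genotype. List length is another: with equally long lists the difference fell from 17 to 9 developmental regulators (counting SD 3), which meets the bound of 9 set beforehand for excluding it but does not pass it by the counting SD. Loss of Utx, the biological explanation, is not supported by its test, since the 60.7% of the 28 regulators unmarked in wild type that had a peak in Utx-cKO restate the gain that prompted it. The gain over wild type was 17 genes in Utx-cKO against 8 in Jmjd3-cKO, which shares its title prefix. The gains were 9 against 8 with equally long lists. At fold enrichment of 4 or more, a cut that is not equal between lists, they were 5 against 6. With n = 1 the 3 explanations cannot be told apart. Nor can they be told apart from library batch, which was not tested, since wild type and Utx-cKO carry different title prefixes.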

How the results depend on the processing

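No paired analysis was possible because each genotype has 1 library and the results come from no test. Of 198 recomputed values that answer a comparison, 117 stayed within their 95% interval, or within 1.5 times for a count, and of 686 others 607 did. Autosomes only moved none of the 16 values it was run on. In each alternative run on the gene lists, housekeeping genes were marked more often than developmental regulators in all 4 genotypes, and each knockout had more marked developmental regulators than wild type, though in Ezh2-cKO by 1 to 4 genes of 45. The alternative with a peak anywhere over the gene and the random lists matched on gene length were added after the data were seen. Unmatched random lists, planned as an alternative, became the main choice. Causes were not tested except where a filter by its construction leaves fewer peaks.

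With fold enrichment of 4 or more, fewer peaks remain by construction: 11716 in wild type, 12498 in Ezh2-cKO, 14455 in Utx-cKO and 13017 in Jmjd3-cKO. Wild-type peaks were overlapped in 95.1%, 98.0% and 96.0% of cases in Ezh2-cKO, Utx-cKO and Jmjd3-cKO, and 10.98%, 21.3% and 13.8% of the knockout peaks lay outside wild-type peaks. Jmjd3-cKO overlapped 85.9% of Utx-cKO peaks, and the converse share was 96.1%. Genes marked by such a peak in Jmjd3-cKO and without a wild-type peak of that strength within 5 kb were 880, and in the converse set 158. Developmental regulators were marked in 15.6%, 20%, 26.7% and 28.9% in wild type, Ezh2-cKO, Utx-cKO and Jmjd3-cKO, and the Utx-cKO difference was 11.1 points. Differences from wild type changed sign for 3 values: TGF-beta and BMP genes to 13.9 points in Ezh2-cKO and 13.9 in Jmjd3-cKO, and matrix degradation to 10.0 in Ezh2-cKO. Fold enrichment at marked genes was lower in wild type as a whole, so this cut is not equal between lists.

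With q of 0.001 or less, peaks numbered 18218 in wild type, 19918 in Ezh2-cKO and 25645 in Utx-cKO. Overlap of wild-type peaks was 88.8%, 93.4% and 88.1%, knockout peaks outside wild type 19.0%, 35.0% and 16.6%, and Utx-cKO with Jmjd3-cKO 67.7% and 92.1%. Shares at gene ends were 61.0%, 57.3%, 46.9% and 59.5%. Developmental regulators in Utx-cKO were marked in 57.8%. Chondrocyte genes in Jmjd3-cKO turned to -3.57 points and matrix degradation in Ezh2-cKO to 3.33.

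With the same number of strongest peaks, overlap of wild-type peaks was 77.4% in Ezh2-cKO, 77.4% in Utx-cKO and 77.8% in Jmjd3-cKO, knockout peaks outside wild type 23.5%, 25.8% and 22.8%, and Utx-cKO with Jmjd3-cKO 75.4% and 78.2%. Counting only these strongest peaks in both lists, genes marked in Utx-cKO and without a wild-type peak within 5 kb were 482, and in the converse set 182. Developmental regulators in Utx-cKO were marked in 57.8%. In Utx-cKO, chondrocyte genes turned to -3.57 points and TGF-beta and BMP genes to -2.78.

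With an overlap of 50%, wild-type peaks were overlapped in 78.6%, 85.3% and 74.0%, knockout peaks lay outside in 35.3%, 53.3% and 23.8%, and Utx-cKO with Jmjd3-cKO gave 46.6% and 87.8%. With peaks within 3 kb merged, the values were 82.5%, 88.5% and 77.7%, then 30.0%, 45.2% and 20.1%, then 54.6% and 90.8%.

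With a window of 1 kb, shares at gene ends were 35.6%, 31.2%, 22.2% and 37.2%, developmental regulators in Utx-cKO 57.8%, and in Ezh2-cKO the Hox difference turned to -2.56 points and matrix degradation to 3.33. With a window of 5 kb, genes marked in wild type and without a knockout peak nearby were 243, 102 and 371 for Ezh2-cKO, Utx-cKO and Jmjd3-cKO, and housekeeping genes were marked in 100% in wild type, Ezh2-cKO and Utx-cKO. With a peak anywhere over the gene, developmental regulators were marked in 57.8%, 66.7%, 86.7% and 73.3% and housekeeping genes in 100% in all 4.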

Other observations

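Ribosomal protein and proteasome genes, which every cell uses, were marked in 115 of 120 cases in wild type and in Jmjd3-cKO and in 116 of 120 in Ezh2-cKO and Utx-cKO. Of homeobox-family genes, 65 of 106 were marked in wild type, 72 in Ezh2-cKO, 88 in Utx-cKO and 81 in Jmjd3-cKO. These 2 lists were written after the shares of the 16 fixed lists were seen. The ribosomal and proteasome list shares 4 genes with the housekeeping list, and 31 of the 106 homeobox genes are in fixed lists, 20 of them among transcription factors of other lineages, so they are not independent of these. Among members marked in wild type, 81.7% of the ribosomal and proteasome genes but 10.8% of the homeobox genes lay above the median of all marked genes. That median, taken over the strongest peak of each marked gene, was a fold enrichment of 6.41.

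Called regions thus lay over genes of general cell upkeep more often than over developmental regulators in all 4 lists, and for the housekeeping and transcription factor lists under each alternative run. A profile that follows Polycomb target genes as a whole, as H3K27me3 does in textbooks, is argued against: the smallest of the 4 differences between ribosomal or proteasome genes and homeobox genes, a list without Hox genes, was 13.6 percentage points in favour of upkeep genes, with intervals that did not overlap in any list, nor when the Hox list was joined (64.8%, 71.0%, 83.4% and 79.3%) in a check added after the result was seen. It stays open for part of the peaks: homeobox genes were marked more often than all genes in Utx-cKO (83.0%, 74.7 to 89.0%, against 67.7%) and Jmjd3-cKO (76.4%, 67.5 to 83.5%, against 63.0%), and in these lists the intervals of Hox genes (84.6% and 87.2%) overlapped those of upkeep genes. The homeobox peaks ranked low there too: 12.5% of the marked homeobox genes in Utx-cKO and 13.6% in Jmjd3-cKO lay above the median of all marked genes. Open chromatin left by the input also stays open: the median fold enrichment at the marked upkeep genes was at least 7.68, above the bound of 4 set beforehand, but marked genes at large passed it too (6.41 in wild type), so the test could not exclude it. A mark of active promoters, through a mislabelled library or antibody, remains a candidate explanation: at least 95.8% of the upkeep genes were marked in each list. Its bounds, set beforehand on this share and on the share of marked upkeep genes above the median of all marked genes, were met. The latter was 81.7% in wild type, 81.0% in Ezh2-cKO, 82.8% in Utx-cKO and 76.5% in Jmjd3-cKO. The high housekeeping shares had been seen before these bounds were written. In wild type 24 of 28 cartilage genes were marked, but 5 of 15 myogenic, 5 of 16 endothelial and 7 of 20 haematopoietic genes. Adipogenic (9 of 14) and Hox genes (29 of 39) were marked more often than these 3 groups. Ezh2-cKO peaks overlapped 99.9% of the wild-type quartile with the highest fold enrichment. These values of the fixed lists and of the overlap were no test of an active mark. Such a mark stays a hypothesis, since no library of another mark was analysed here, and the word H3K27me3 in the report is that of the labels.

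The 55 genes marked in wild type and in no knockout list included 4 Y-linked genes, Kdm5d, Eif2s3y, Uty and Ddx3y, with fold enrichments of 4.41, 2.796, 3.295 and 3.656. Their peaks lay at 897881 to 1286590, and no Y-linked gene was marked in a knockout list. The other peaks on chromosome Y all lay at 90797347 to 90828956: 2 in wild type, 4 in Utx-cKO (1 with fold enrichment 5.55) and 2 in Jmjd3-cKO. The knockout lists thus held no peak in the region of the 4 genes. The sex of the animals was tested through Xist, with the bound set beforehand that a wild-type peak there would count against it, and the wild-type list did hold one, with fold enrichment 4.02. The knockout lists held one too (5.00, 6.85 and 4.80), and such a peak means an active Xist gene only if the mark is an active one, so after the values were seen the bound was judged wrong and sex stays open, with a library from both sexes among the possibilities. Strain or copy-number differences in gene clusters may also play a part, but the test left this open: 28.6% of the genes marked in wild type with no Utx-cKO peak within 5 kb had another within 1 Mb, above the 95th percentile of 1000 random draws (19.0%) and, in a check added after the result was seen, still above it without Y-linked genes (23.7% against 18.6%), whereas 26.1% against Ezh2-cKO and 32.1% against Jmjd3-cKO were below theirs (29.4% and 37.5%). Loss of Ezh2, Utx or Jmjd3 was not tested as an explanation for this pattern.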
